A study of Mus musculus with 42 samples.

How the data were processed

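The series held RNA sequencing of placentas collected at embryonic day 12.5 from wild-type CF1 mice, an outbred stock, whose treatment was given as saline or as oxycodone, an opioid analgesic. The labels gave a treatment and a sex for each of 42 libraries, 10 saline female, 11 oxycodone female, 10 saline male and 11 oxycodone male, and a number between 1 and 73 that was used once each. The sample titles also held a second index between 1 and 42, used once each, whose meaning was not given. They gave no dose, dosing schedule, dam, litter, collection date or sequencing batch. Per the labels, total RNA was extracted from snap-frozen tissue with an AllPrep kit and 850 ng was made into TruSeq libraries.

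The deposited matrix held raw counts, whole numbers of fragments per gene, with no normalization. Per the file headers, these counts were made with featureCounts 2.0.0 on read pairs, summed over exons by gene identifier in Ensembl release 99 of GRCm38, with no option for strand, multi-mapping reads or overlapping genes. The processing notes of the authors gave HISAT2 2.0.5 for alignment to GRCm38 and Subread 2.0.1, a version of the featureCounts package that differs from that in the header. Fragments were therefore not assigned by strand, so antisense transcription may enter a gene's count. Fragments aligning to several places were not counted, which limits the values of close paralogs such as the prolactin, Psg, Ceacam, cathepsin and granzyme families. The matrix held 55348 genes, of which 55107 had a symbol in the annotation, and 0 mitochondrially encoded genes.

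Depth ranged from 27327803 to 37297690 counted fragments per library. The floor of 3 counts corresponded to 0.110 CPM (counts of a gene scaled to library size, edgeR's cpm) in the shallowest library. Intervals and floors built on counts cover counting error only. The sex in the labels was checked in every library by Xist against the summed CPM of 4 Y-linked genes. The other X-linked genes of the sex check list were compared between the sexes only. The 200 pairs of libraries within groups were checked for copied columns.

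Genes were filtered by edgeR's filterByExpr by group, with a minimum count of 10 and a minimum total of 15, which left 17700 genes. Libraries were scaled by TMM. Gene tests used edgeR 4.0.16 in R 4.3.3, with a quasi-likelihood F test on all 42 libraries in a single fit, a mean per group, and robust estimates. The newer quasi-likelihood method was used (legacy=FALSE), which is not the default of this version; the legacy method was an alternative. The p-values were adjusted over tested genes by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were oxycodone against saline in females, in males and averaged over the sexes, the difference of the oxycodone effect between the sexes (female minus male), and male against female under each treatment. Log2 fold changes are edgeR's, with standard errors (SE), and group values are mean CPM with the standard deviation (SD) over 10 or 11 libraries.

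Gene lists numbered 39, of which 2 served the sex check and 36 were tested, since the list of mitochondrially encoded genes had no gene in the matrix. Each was tested with camera of limma 3.58.1, a competitive two-sided test with a preset correlation of 0.01, adjusted over the 36 lists in each comparison. Camera with an estimated correlation and fry, a self-contained test, were alternatives. The score of a list in a library was the mean log2 CPM (prior count of 2) of its members. Score differences were tested by two-sided permutation of libraries (100000 resamples), with 95% bootstrap intervals (2000 draws).

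These comparisons, tests, lists and most alternatives were fixed before the data were examined. So was the rule for genes named in the text. It takes, among genes past the threshold with a mean of at least 1 CPM and a symbol that is not a predicted or clone name, the 12 with the smallest p in each direction. Where fewer than 6 genes passed, it takes the 5 smallest p in each direction, as values only. It adds up to 4 members with the smallest p from each list described, the opioid receptors and the sex check genes. Any other gene is said to have been chosen after its values were seen. The sexes were also compared by the correlation of their log2 fold changes over genes.

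Alternatives fixed beforehand were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-voom with sample quality weights, and the legacy quasi-likelihood without robust estimates. The DESeq2 Wald test was run on the 40319 genes with any count, with the filter of its own. Others changed the filter (none, or a mean of at least 1 CPM), kept only the groups compared, set a fold minimum of 1.2, or left out each library in turn. Further ones added up to 5 surrogate variables from sva 3.50.0, a decidual score or an erythroid score. Alternatives chosen after seeing the data were the legacy method with robust estimates, a term for the block of library numbers (up to 36, or 43 and above), each block alone, a yolk sac score as a term, the fit without saline female 67, alone or with an estimated correlation, the DESeq2 Wald test adjusted over the 17700 genes, the list counts without each library, and the permutation of list scores. The correlations of named genes with the yolk sac score and the use of the second index were also chosen after seeing the data. The comparisons were repeated on 100 splits of the libraries, the real one included, or 50 for surrogate variables. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 served the permutation tests, and matplotlib 3.10.9 the plots.

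The comparisons were tested on simulated data, drawn from negative binomial distributions with the means, dispersions and depths estimated here, in which 200 genes with a mean of at least 1 CPM were raised or lowered in the oxycodone libraries of a single sex. The simulated libraries of a group were independent of each other, whereas real libraries with neighbouring numbers were alike. The shares called may therefore overstate what the real tests could call, and they do not cover changes in genes under 1 CPM. In the female comparison, 50.7% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 98.5% of those changed 4-fold were called. In the male comparison the shares were 47.8%, 91.0% and 98.5%. Genes that had not been changed made up 4.19% of the female calls and 3.66% of the male calls. The p-values measure the spread between these libraries only, since the labels do not say which placentas shared a dam or litter.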

Results

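Placentas of saline-treated and oxycodone-treated mice were compared at embryonic day 12.5, separately in females and males, by counting fragments per gene in 42 libraries. The groups held 10 saline female, 11 oxycodone female, 10 saline male and 11 oxycodone male libraries. Counted fragments per library ranged from 27327803 to 37297690, and 24909 to 27809 genes had at least 1 count. The 10 most abundant genes took 6.22% to 19.1% of the counts of a library. The common biological coefficient of variation was 0.343, and the median SE of a log2 fold change in the female comparison was 0.15 among genes with a mean of at least 1 CPM. The sex read from Xist and the Y-linked genes matched the label in all 42 libraries. Of the 200 pairs of libraries within groups, 0 had identical columns.

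In female placentas, 3 families of secreted placental genes were higher with oxycodone than with saline, and the markers of the visceral yolk sac, an extraembryonic tissue attached beside the placenta, were lower. The prolactin family, hormones secreted by trophoblast and decidua, rose, with a mean log2 fold change of 0.39 over 24 measured members, of which 20 were higher. The pregnancy-specific glycoproteins and placental Ceacam genes rose by a mean of 0.36, with 19 of 21 members higher. The placental cathepsins, a rodent cluster of trophoblast proteases, rose by a mean of 0.55, with all 8 measured members higher. The 15 yolk sac markers, most of them serum and lipid-carrying proteins such as Afp, fell by 0.86 on average, and all 15 were lower. These 4 lists passed only with a preset correlation (adjusted p = 0.247 with an estimated correlation for each).

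Among the prolactin family in females, Prl8a6 (chromosome 13, 27432681 to 27438688, ENSMUSG00000021345) measured 97.8 ± 40.04 CPM (mean ± SD, n = 11) with oxycodone and 49.2 ± 20.9 CPM (n = 10) with saline. Its log2 fold change was 0.99 (SE 0.26), all 11 oxycodone libraries lay above the saline median, and 8 lay above every saline library. Prl8a8 measured 482 ± 325 CPM against 213 ± 97.9 CPM, a log2 fold change of 1.18. Prl3a1 and Prl3c1, the latter also on the decidual list, had log2 fold changes of 1.51 and 0.85. Adjusted over the list alone, 4 of the 24 prolactin members passed the threshold, all higher, with a smallest adjusted p of 0.011, while 0 passed over all genes. Among the Ceacam and Psg genes, Ceacam12 had a log2 fold change of 1.02 (SE 0.41), Ceacam11 of 0.69, Psg16 of 0.84 and Ceacam13 of 0.63, and 0 members passed adjusted over the list alone or over all genes. Of the cathepsins, Cts3 (chromosome 13, 61564630 to 61570127) measured 2309 ± 1122 CPM against 1458 ± 654 CPM, a log2 fold change of 0.66 (SE 0.31). Cts6, Cts7 and Cts8 had log2 fold changes of 0.92, 0.92 and 0.81, and 0 cathepsins passed adjusted over the list alone or over all genes. Of the yolk sac markers, Amn, a cubilin partner in protein uptake, had a log2 fold change of -1.19, Rbp4 of -1.05, Hnf4a of -0.74 and the iron carrier Trf of -0.56, and 0 of 15 passed by either count.

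The camera tests of these 4 lists in females, with a preset correlation, gave adjusted p-values of 1.08e-10 for the prolactin family, 8.92e-10 for the glycoproteins, 2.96e-05 for the cathepsins and 4.52e-13 for the yolk sac markers. Each call was lost with the correlation estimated from the data (adjusted p = 0.247 with an estimated correlation). The mean list score lay above the saline median in 10 of 11 oxycodone libraries for the prolactin family, 8 of 11 for the glycoproteins and 10 of 11 for the cathepsins, and below it in 9 of 11 for the yolk sac markers. A permutation of the 21 female libraries, chosen after seeing the data, gave p = 0.0277 for the cathepsin score difference of 0.54 (95% bootstrap interval 0.12 to 0.94), p = 0.102 for the prolactin score, p = 0.099 for the glycoprotein score and p = 0.111 for the yolk sac score; 0 of the 36 lists passed after adjustment, the smallest adjusted p being 0.653. Within the libraries numbered up to 36 and those numbered 43 and above, the prolactin means were 0.31 and 0.27, the glycoprotein means 0.38 and 0.29, and the cathepsin means 0.57 and 0.42, each past the threshold of the preset test. The yolk sac decrease did not hold in both blocks: the mean was -2.41 in libraries numbered up to 36 and -0.15 (adjusted p = 0.753) in those numbered 43 and above.

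**Figure D1:**
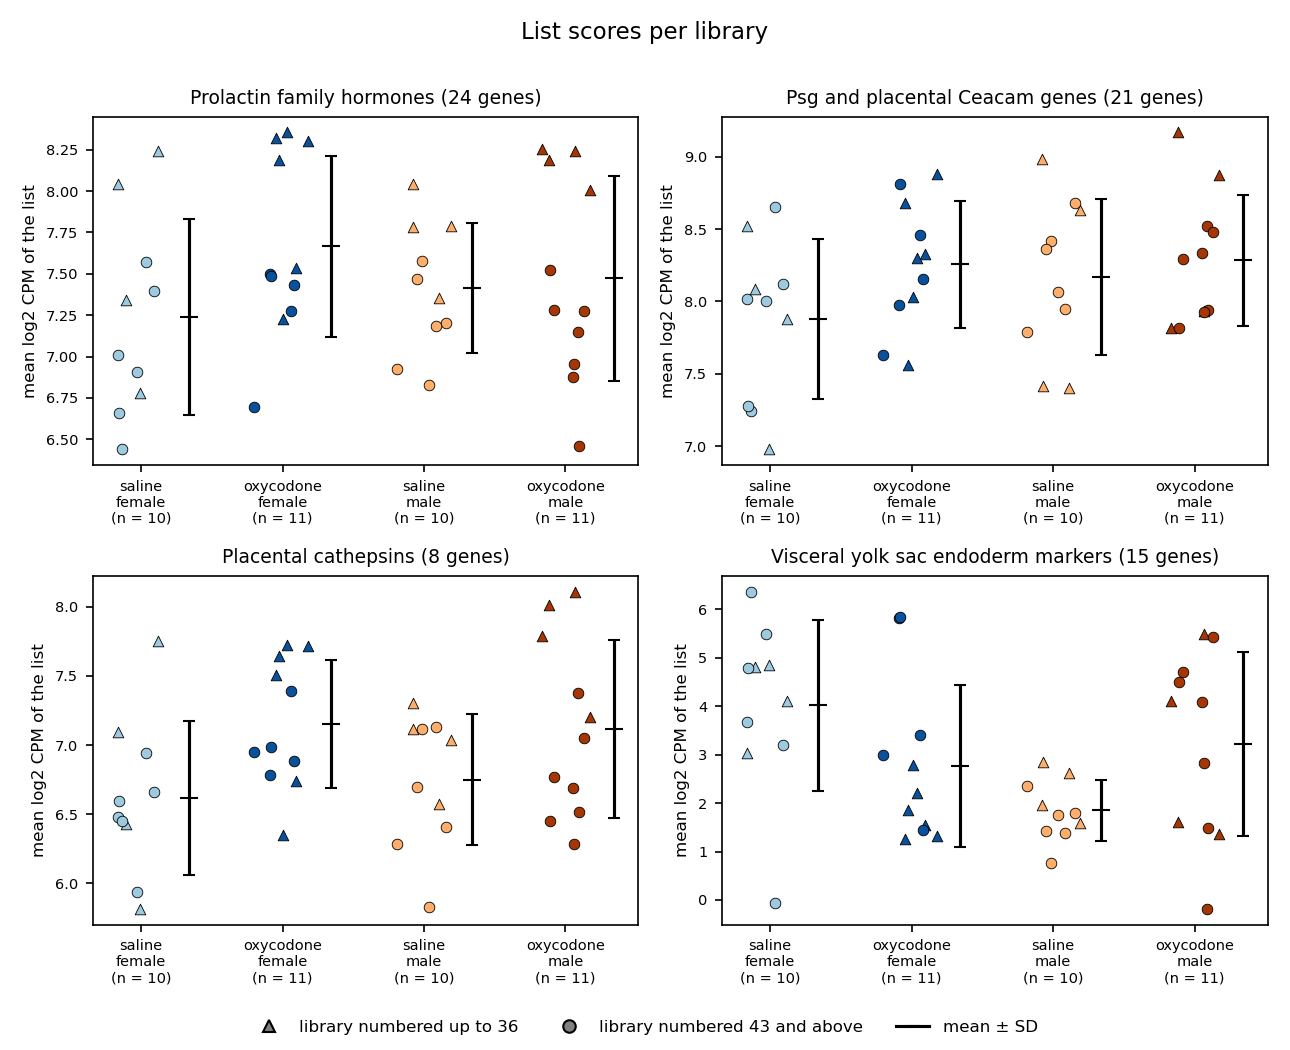
Mean log2 CPM per library for the 4 lists named in each panel title, by group (n on the axis), with mean ± SD bars; triangles are libraries numbered up to 36 and circles those numbered 43 and above. The oxycodone female means are 7.67 (prolactin family) and 7.15 (cathepsins) against 7.24 and 6.62 in saline females, and the yolk sac score spans -0.06 to 6.36 within the saline females alone.

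The genes with the smallest p in females, given as values since 0 genes passed the threshold, included the detoxifying enzyme Mgst1, at 12.8 ± 5.84 CPM with oxycodone and 7.01 ± 2.45 CPM with saline (log2 fold change 0.87, SE 0.24). C5ar2, a complement anaphylatoxin receptor, had a log2 fold change of 0.78 (SE 0.23), Stmn2, a neuronal microtubule regulator, of 0.60, and Hacd2, an enzyme of fatty acid elongation, of 0.26. Stmn2 passed the threshold adjusted over the list of 5 neural markers alone (adjusted p = 0.0125), whose mean of 0.09 did not pass; it was higher than the saline median in 10 of 11 oxycodone libraries. The 5 lowest were the chemokine Cxcl14 (-4.34), the secreted Wnt antagonist Sfrp4 (-4.38), the protease Klk15 (-2.91), the annexin Anxa8 (-2.10) and Vwa7 (-0.54). A single library, saline female 67, held 108 CPM of Cxcl14, against a saline female mean of 11.3 ± 33.99 CPM, and without it the log2 fold changes were -0.04 for Cxcl14, -0.29 for Sfrp4, 0.15 for Klk15 and -0.70 for Anxa8. Past an adjusted p of 0.05, edgeR called 0 of 17700 genes (369 at an unadjusted p under 0.05, smallest adjusted p 0.198), as did limma-voom (579). The 369 were 2.08% of the genes, fewer than a p under 0.05 gives by chance for unchanged genes. The fit with surrogate variables gave 1679 of 17700 genes, more than chance gives. The share therefore depended on the model and does not measure how many genes changed. DESeq2 called 0 of the 40319 genes with any count (617 at an unadjusted p under 0.05, of which 377 among the 17700). With surrogate variables the count was 14, without a filter on low counts it was 2, Ear1 (-5.49) and Gm4737 (4.86), and in the libraries numbered up to 36 it was 1, Gm14253; these 3 were chosen after their values were seen.

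A further 6 lists passed the preset test in females with means under 0.20 in size, and each call rested on single libraries. The hypoxia and glycolysis genes fell by 0.11 (21 of 25 lower, adjusted p = 0.0109; adjusted p = 0.418 with an estimated correlation), with Pfkp at -0.20 and Pgam1 at -0.16. The oxidative stress defence genes fell by 0.14 (14 of 15 lower, adjusted p = 0.0125; adjusted p = 0.247 with an estimated correlation), with Nqo1 at -0.20 and Gsr at -0.15. Leaving out saline female 67 took these to means of -0.05 (adjusted p = 0.176) and -0.05 (adjusted p = 0.0584), and leaving out oxycodone female 20 or oxycodone female 54 also ended them (adjusted p = 0.054 and 0.0502). The unfolded protein and integrated stress response genes rose by 0.06 (16 of 20 higher, adjusted p = 0.0109; adjusted p = 0.628 with an estimated correlation), with Herpud1 at 0.41 and Manf at 0.27. That call ended without saline female 6, 23, 63 or 71 or oxycodone female 12 (adjusted p 0.0737 to 0.167). The interferon response genes fell by 0.11 (15 of 18 lower, adjusted p = 0.0249; adjusted p = 0.739 with an estimated correlation), with Oasl2 at -0.27 and Oas1a at -0.17. The cholesterol synthesis genes fell by 0.13 (16 of 21 lower, adjusted p = 0.0272; adjusted p = 0.67 with an estimated correlation), with the LDL receptor regulator Pcsk9 at -1.26 and Fdps at -0.30. The steroid hormone synthesis genes fell by 0.19 (12 of 14 lower, adjusted p = 0.0477, and adjusted p = 0.334 with an estimated correlation). Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, was at -0.49, and Fdxr, a reductase in its electron supply, was at -0.32.

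The last 3 of these calls ended in 9, 8 and 18 of the 42 fits without 1 library. For the interferon list the libraries were oxycodone female 12, 13, 26 and 48 and saline female 23, 51, 63, 67 and 71 (adjusted p 0.0576 to 0.356). For the cholesterol list they were oxycodone female 12, 20, 22 and 54 and saline female 6, 44, 63 and 67 (adjusted p 0.053 to 0.276). For the steroid list they were oxycodone female 12, 22, 48, 54, 69 and 72, saline female 1, 15, 44, 67 and 71, saline male 18, 24 and 64, and oxycodone male 11, 21, 35 and 70 (adjusted p 0.0501 to 0.216). Within the blocks numbered up to 36 and 43 and above, the means were -0.09 and -0.07 (hypoxia), 0.11 and 0.03 (unfolded protein), -0.03 and -0.17 (oxidative stress), -0.06 and -0.12 (interferon), -0.17 and -0.08 (cholesterol) and -0.02 and -0.35 (steroid). Only the unfolded protein, oxidative stress and steroid lists passed in a block, in each case that numbered 43 and above.

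The other 26 lists did not pass in females, among them the markers of the placental zones and of blood and immune cells; this does not show that they were unchanged. For trophoblast and decidua, the means were 0.16 for junctional zone markers, -0.04 for labyrinth markers, -0.07 for giant cell markers, -0.05 for stem cell genes, -0.21 for decidual stroma and -0.49 for uterine epithelium. The decidual list differed in sign between its median of -0.26 and its test, which pointed up, and 5 other lists with means under 0.25 in size did so too. The uterine values depended on saline female 67, which lay apart in these markers. In the fit without it, chosen after seeing the data, the decidual mean turned to 0.55 (adjusted p = 5.6e-11; adjusted p = 0.0242 with an estimated correlation), the uterine epithelium mean was -0.19 and the natural killer mean was 0.59 (adjusted p = 7.42e-06; adjusted p = 0.395 with an estimated correlation). Blood and immune markers had means of 0.18 (uterine natural killer cells, adjusted p = 0.0555), -0.19 (macrophages), 0.39 (neutrophils), -0.25 (lymphocytes) and -0.04 (erythroid cells). Endothelial, smooth muscle and extracellular matrix genes had means of -0.04, -0.16 and -0.13, and angiogenic factors -0.03. Cell cycle genes (-0.10, adjusted p = 0.0638, and 0.019 without saline female 67; adjusted p = 0.823 with an estimated correlation), ribosomal proteins (0.06), nuclear oxidative phosphorylation genes (0.02), immediate early genes (-0.08) and cytokines (-0.01) did not pass. Drug efflux genes (-0.09), the list of opioid receptors and peptides (0.24) and serotonin and catecholamine genes (-0.24) did not pass either. Of the 10 members of the opioid list only 4 were tested, and Oprm1, Oprk1, Oprd1 and Oprl1 were not among them. Imprinted genes and nutrient transporters had means of -0.0031 and -0.005.

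In male placentas, the yolk sac markers were higher with oxycodone, by a mean log2 fold change of 2.11, and all 15 rose adjusted over the list alone, though 0 did over all genes. These markers moved together over libraries and do not count as separate results. Apob and the retinol carrier Rbp4 had log2 fold changes of 2.69 and 2.35, and Apom of 1.79. Afp, chosen after its values were seen, measured 102 ± 74.1 CPM with saline (n = 10) and 625 ± 632 CPM with oxycodone (n = 11). This was the only list to pass with both the preset correlation (adjusted p = 9.29e-33) and an estimated one (adjusted p = 0.0347 with an estimated correlation). The score lay above the saline median in 7 of 11 oxycodone males and above every saline male in 6, with a difference of 1.37 (95% bootstrap interval 0.25 to 2.52; permutation p = 0.0438, adjusted p = 0.989 over 36 lists). It was higher in both blocks, with means of 1.72 and 2.47.

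Of the cathepsins, 5 of 8 were higher in oxycodone males and the list rose by a mean of 0.44 (adjusted p = 0.0269; adjusted p = 0.968 with an estimated correlation). Cts7 had a log2 fold change of 1.71 (SE 0.57) and passed adjusted over the list alone (adjusted p = 0.0375) but not over all genes; Cts8 was at 0.89. The increase did not hold in both blocks: the cathepsin mean was 0.72 in libraries numbered up to 36 and 0.17 (adjusted p = 0.989, with the test pointing down) in those numbered 43 and above. The unfolded protein genes rose by 0.11 (16 of 20 higher, adjusted p = 0.00634; adjusted p = 0.968 with an estimated correlation), with Herpud1 at 0.43 and Creld2 at 0.28, and had means of 0.29 and 0.0023 in the blocks. The cell cycle genes fell by 0.09 (19 of 20 lower, adjusted p = 0.00634; adjusted p = 0.968 with an estimated correlation), with Ccna2 at -0.19, and had means of -0.34 and -0.0013 in the blocks. Single libraries ended each of these calls: oxycodone male 11, 21, 25, 35 and 53 and saline male 5, 43, 45 and 61 for the cathepsins (adjusted p 0.0698 to 0.324), oxycodone male 25 and 35 and saline male 5, 24 and 61 for the unfolded protein genes (0.0577 to 0.486), and oxycodone male 11, 25, 35 and 53 and saline male 5, 45 and 64 for the cell cycle genes (0.0758 to 0.324). The other 32 lists did not pass (smallest adjusted p 0.103), among them the prolactin family (mean 0.15) and the glycoproteins (0.11).

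The male genes with the smallest p were again given as values. Higher with oxycodone were Maob, which breaks down monoamines, at 7.13 ± 6.14 CPM against 1.35 ± 0.641 CPM (log2 fold change 2.40), the apolipoprotein Apoa4 (2.49), complement factor Cfi (2.63), the heme carrier Hpx (1.79) and the myeloid lectin receptor Clec12a (0.90). Apoa4 is a yolk sac marker, and Maob, Cfi and Hpx, which are not on that list, had correlations of 0.967, 0.986 and 0.885 with the yolk sac score over the 42 libraries. Lower were Trim12c (-1.38), Prkcq (-0.60) and 3 platelet genes, Gp1ba (-0.54, SE 0.19), Pf4 (-0.73, SE 0.26) and Mmrn1 (-0.55, SE 0.20). Trim12c lay below the saline median in all 11 oxycodone males. Maob passed adjusted over the serotonin and catecholamine list alone (adjusted p = 0.0137), whose mean of 0.16 did not pass, and lay above the saline median in 10 of 11 oxycodone males. Past an adjusted p of 0.05, edgeR called 0 genes (305 at an unadjusted p under 0.05), as did limma-voom (711) and DESeq2 (312 among the same 17700 genes, 614 among 40319). The 305 were 1.72% of the tested genes, again fewer than chance gives for unchanged genes, but with surrogate variables there were 1055, more than chance gives.

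Averaged over the sexes, 1 gene passed, the predicted gene Gm14253 (chromosome 2, 156347202 to 156347840), which was chosen after its values were seen because it falls outside the naming rule. It was lower with oxycodone, by a log2 fold change of -3.73 (SE 0.70, adjusted p = 0.0438). It exceeded 1 CPM in 4 of 10 saline females, 4 of 10 saline males, 0 of 11 oxycodone females and 1 of 11 oxycodone males. It lay below the saline median in all 11 oxycodone females and 8 of 11 oxycodone males. Those medians were low, 0.36 CPM in saline females and 0.093 CPM in saline males. The latter was under the floor of 0.110 CPM, so the male ranks cannot tell a decrease from counting error. The call rested on which libraries and test were used: it stayed in 12 of the 42 fits without 1 library (adjusted p 0.0203 to 0.213 in the 41 that tested the gene), while the log2 fold change stayed between -3.83 and -3.27. Leaving out any of the 22 oxycodone libraries ended it (without oxycodone male 57 the gene failed the filter), as did leaving out saline female 1, 6, 15 and 23 and saline male 16, 24, 43 and 64. The highest adjusted p came without saline female 23 (0.213) and without saline male 24 (0.182), which are neighbours in number. A shared litter or inherited variation in this outbred stock was not tested for this gene. Limma-voom called 1 gene, Tpm3-rs7 (-4.04, adjusted p = 0.0133), and DESeq2 called 3, Gm14253 (-3.78, adjusted p = 0.0249), C5ar2 and Apol11b (-1.62, adjusted p = 0.0294); Tpm3-rs7 and Apol11b were also chosen after their values were seen. At an unadjusted p under 0.05, edgeR gave 428 of 17700 genes, limma-voom 755 and DESeq2 427, or 751 of 40319. The 428 were 2.42% of the tested genes, fewer than chance gives for unchanged genes, but with surrogate variables there were 1638, more than chance gives. With DESeq2 adjusted over the 17700, 2 genes passed. Over all alternatives the adjusted p of Gm14253 ran from 0.000469 to 1.

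C5ar2 (chromosome 7, 16234585 to 16244154, ENSMUSG00000074361) had the smallest p among genes of the naming rule, with a log2 fold change of 0.77 (SE 0.16, p = 2.38e-05, adjusted p = 0.176). It measured 5.93 ± 2.47 CPM in oxycodone females (n = 11) against 3.47 ± 1.13 CPM in saline females (n = 10), and 5.85 ± 1.54 CPM in oxycodone males (n = 11) against 3.43 ± 1.37 CPM in saline males (n = 10). Of the oxycodone libraries, 9 of 11 females and 11 of 11 males lay above the saline median of their sex. Its average log2 fold change was 0.68 in the libraries numbered up to 36 and 0.88 in those numbered 43 and above. The Wald test of DESeq2 gave an adjusted p of 0.0372, within a range of 0.0372 to 1 over all alternatives. The next highest were Mgst1 (0.68), Clec12a (0.68), Tex13b (1.29) and Igfbp7, a secreted growth factor binding protein (0.33). The lowest were Cxcl14 (-2.42, and -0.27 without saline female 67), Vwa7 (-0.36) and 3 genes close together on chromosome 7, Trim68 (-0.76), Hbb-bh0 (-0.94) and Trim12c (-1.08).

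**Figure D2:**
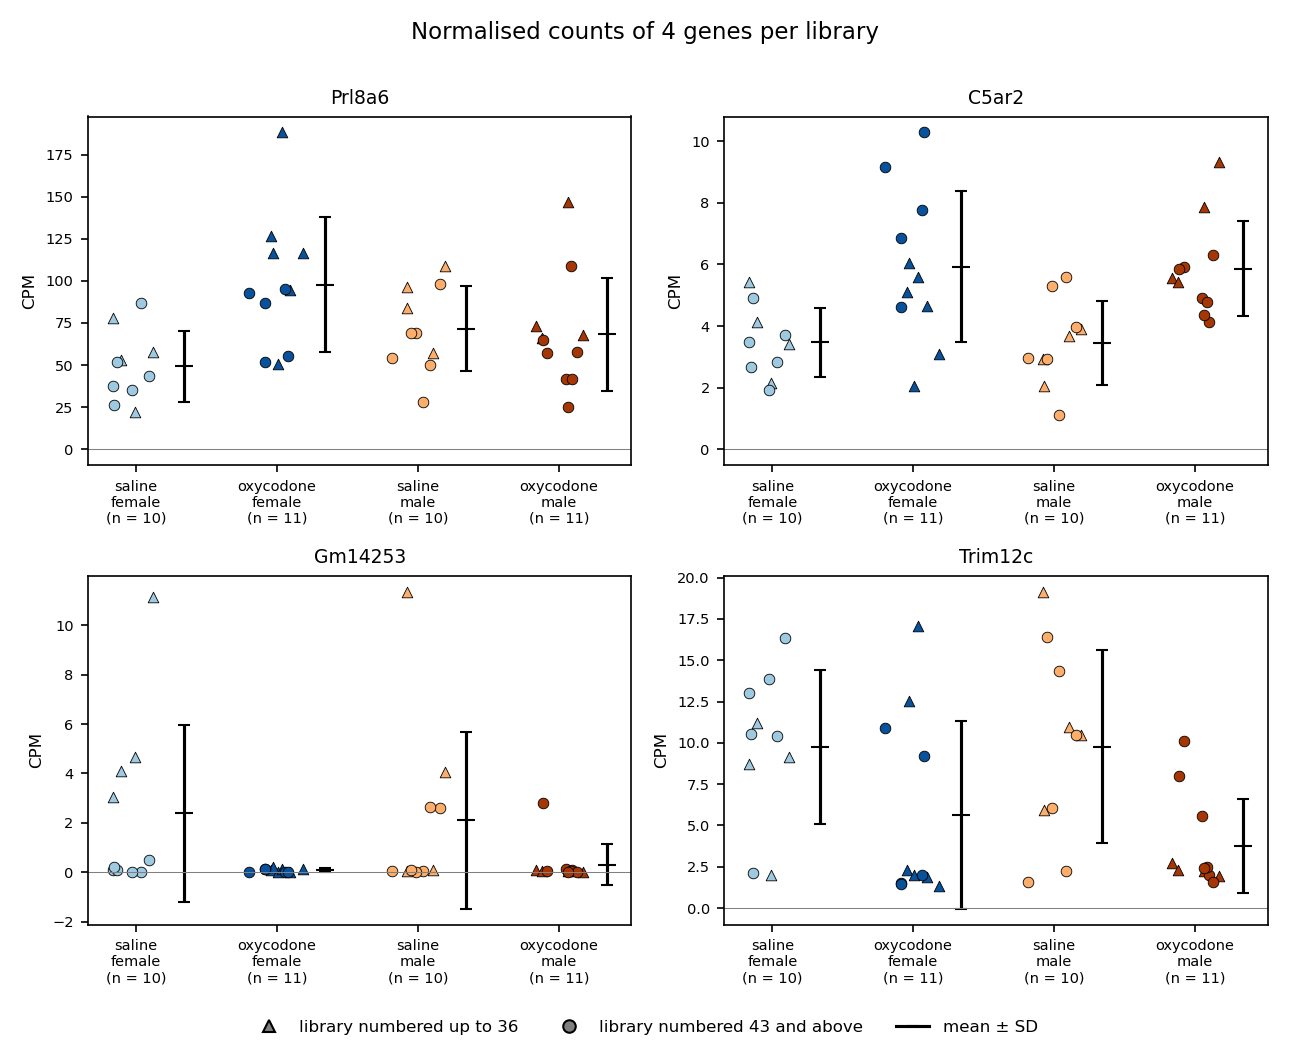
Normalised counts (CPM) per library of Prl8a6, C5ar2, Gm14253 and Trim12c by group (n on the axis), with mean ± SD bars; triangles are libraries numbered up to 36 and circles those numbered 43 and above. All 11 oxycodone males lie above the saline male median of C5ar2, and 8 saline libraries hold more than 1 CPM of Gm14253.

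Averaged over the sexes, 8 of the 36 lists passed the preset test, and 0 passed with an estimated correlation. The cathepsins rose by 0.49 with 8 of 8 members higher (adjusted p = 6.29e-06; adjusted p = 0.21 with an estimated correlation), and Cts7 (1.31), Cts3 (0.57) and Cts8 (0.85) passed adjusted over the list alone, with 0 over all genes. The permutation p of the cathepsin score was 0.0101 (adjusted p = 0.365), and the block means were 0.64 and 0.30, the latter not past the preset test (adjusted p = 0.214). The glycoproteins rose by 0.24 with 19 of 21 higher (adjusted p = 7.06e-08; adjusted p = 0.603 with an estimated correlation), Ceacam12 being at 0.72. The prolactin family rose by 0.27 with 19 of 24 higher (adjusted p = 4.97e-07; adjusted p = 0.603 with an estimated correlation), Prl5a1 being at 0.51. Their block means were 0.35 and 0.14 for the glycoproteins, and 0.35 and 0.07 (adjusted p = 0.11) for the prolactin family.

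The unfolded protein genes rose by 0.09 on average (15 of 20 higher, adjusted p = 0.000221; adjusted p = 0.603 with an estimated correlation), with Herpud1 at 0.42 and Manf at 0.24. The cell cycle genes fell by 0.10 (19 of 20 lower, adjusted p = 0.00141; adjusted p = 0.738 with an estimated correlation), with Rrm2 at -0.30. The cholesterol genes fell by 0.07 (16 of 21 lower, adjusted p = 0.0131; adjusted p = 0.738 with an estimated correlation), with the sterol carrier Stard4 at -0.34. The hypoxia genes fell by 0.06 (20 of 25 lower, adjusted p = 0.0175; adjusted p = 0.614 with an estimated correlation), with Ddit4 at -0.19 and Pgam1 at -0.16. The natural killer cell markers rose by 0.24 (10 of 11 higher, adjusted p = 0.0346; adjusted p = 0.738 with an estimated correlation), with Gzma at 0.91. In the blocks numbered up to 36 and 43 and above, the means were 0.20 and 0.01 (unfolded protein), -0.18 and -0.04 (cell cycle), -0.10 and -0.05 (cholesterol), -0.03 and -0.07 (hypoxia) and 0.52 and -0.16 (natural killer cells), so the natural killer increase did not hold in both. Single libraries ended 3 of these calls: the natural killer call in 20 of the 42 fits (adjusted p 0.0519 to 0.153), the hypoxia call without saline female 67, oxycodone female 20 or oxycodone male 11 (0.0521 to 0.157), and the cholesterol call without oxycodone female 22 or 54, oxycodone male 21, saline female 63 or saline male 45 or 64 (0.0505 to 0.0866). The 20 libraries for the natural killer call were oxycodone male 11, 21, 25, 35, 50, 70 and 73, saline male 5, 24, 45, 61 and 68, saline female 6, 15, 44, 51, 63 and 71, and oxycodone female 20 and 72.

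The oxycodone effect differed between the sexes for the yolk sac markers, lower in females and higher in males. The difference (female minus male) averaged -2.97 log2 units, and all 15 members passed adjusted over the list alone, with 0 over all genes. The members moved together over libraries, so the 15 do not count as separate results. Their median pairwise correlation was 0.471 in saline males and 0.900 to 0.928 in the other groups. Amn was at -2.77, Rbp4 at -3.40, Apom at -2.59 and the fibrinogen chain Fgb at -3.37. The list passed with the preset correlation (adjusted p = 1.27e-52) and an estimated one (adjusted p = 0.00179 with an estimated correlation), in both blocks (means -4.13 and -2.63). The opposite directions held only in the libraries numbered up to 36: in those numbered 43 and above, the female mean was -0.15 (adjusted p = 0.753), and the difference came from the males (2.47). Its score difference was -2.62 (95% bootstrap interval -4.35 to -0.77; permutation p = 0.0106, adjusted p = 0.381). The saline groups already lay apart: the score was 4.02 ± 1.76 in saline females (n = 10) and 1.85 ± 0.62 in saline males (n = 10), against 2.77 ± 1.67 in oxycodone females (n = 11) and 3.22 ± 1.90 in oxycodone males (n = 11).

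The prolactin family and the glycoproteins also passed the preset test of the sex difference, with means of 0.24 (adjusted p = 1.13e-05; adjusted p = 0.784 with an estimated correlation) and 0.25 (adjusted p = 0.00187; adjusted p = 0.949 with an estimated correlation). Prl3a1 was at 1.82, Prl8a8 at 1.02 and Psg16 at 0.84. Neither held in both blocks: the prolactin mean was -0.07 in libraries numbered up to 36 and 0.39 in those numbered 43 and above, and the glycoprotein means were 0.07 (adjusted p = 0.73) and 0.30. The glycoprotein call ended without oxycodone male 11, saline male 18 or 43, or saline female 6, 63 or 71 (adjusted p 0.0587 to 0.135). The other 33 lists did not pass (smallest adjusted p 0.077). Of single genes, Prl8a6 had a difference of 1.06 (SE 0.36), Prkcq of 0.74, Tmem158 of 0.39 and Purb of 0.21. Ddx3y (3.72) also ranked among these, a Y-linked gene with near-zero counts in females. The lowest were the plasma proteins Cfi (-3.54), Cpn1 (-3.34) and Proz (-2.08), with Maob (-3.28) and the sodium pump subunit Fxyd2 (-3.07), each at an adjusted p of 0.67. These 5 followed the yolk sac score over the 42 libraries (r of 0.986, 0.951, 0.885, 0.967 and 0.894 in that order), so their difference cannot be told apart from that of the yolk sac markers. Maob also passed adjusted over the serotonin and catecholamine list alone (adjusted p = 0.0108), though the list did not pass. Past an adjusted p of 0.05, edgeR called 0 genes (306 at an unadjusted p under 0.05), as did limma-voom (563) and DESeq2 (307 among the same 17700 genes, 567 among 40319). The 306 were 1.73% of the tested genes, fewer than chance gives for unchanged genes, but with surrogate variables there were 1095, more than chance gives.

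Over the 17700 genes, the female and male log2 fold changes had a Pearson's r of 0.049 and a Spearman's rho of 0.229, and 59.9% had the same sign; genes are not independent replicates. Among genes with a mean of at least 1 CPM, r was 0.111. At an unadjusted p under 0.05 in both sexes there were 47 genes, against 6.36 for independent lists, and 18 of the 47 moved the same way. The 6.36 takes genes as independent, and the overlap was not compared with other splits, so this excess has no measure of chance.

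Male and female placentas under saline differed in 11 genes, of which 5 were higher and 6 lower in males. The Y-linked genes Kdm5d, Eif2s3y, Uty, Ddx3y and the predicted gene Gm29650 rose in males. Ddx3y (99.4 ± 38.2 CPM) was at least 10596-fold higher and Uty (21.5 ± 8.43 CPM) at least 2287-fold higher, against a floor of 3 counts over the saline females. Xist, the RNA that silences an X chromosome, fell by 6.05 on the log2 scale in males, and the X-linked translation factor Eif2s3x fell by 0.44 (adjusted p = 0.0499), lower than the female median in 10 of 10 males. The other 4 genes, chosen after their values were seen together with Gm29650, were Ftcd (-3.70), Bhmt (-1.54), C9 (-3.38) and Slc22a6 (-3.65), metabolic and plasma protein genes that averaged 0.309 to 0.359 CPM over all 42 libraries and had correlations of 0.877, 0.685, 0.939 and 0.938 with the yolk sac score. Kdm6a, Kdm5c and Ddx3x, also X-linked, were at 0.01, -0.25 and 0.07 and did not pass.

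The saline count depended on single libraries: it was 107 without saline female 44, 57 without saline female 1, 48 without oxycodone female 48 and 18 without saline female 47, and 6 or 7 in 17 of the 42 fits without 1 library. DESeq2 gave 116 genes, or 103 adjusted over the 17700, and limma-voom 20. Of the lists, the yolk sac markers fell in males by a mean of 2.71 on the log2 scale (adjusted p = 4.89e-38, and adjusted p = 0.0159 with an estimated correlation), with 10 of 10 males below the female median. Adjusted over the list alone 15 of 15 passed, but they moved together over libraries and do not count as separate results. The glycoproteins rose by 0.26 with 20 of 21 higher (adjusted p = 6.94e-05), and the interferon response genes and macrophage markers fell, by 0.20 (17 of 18 lower, adjusted p = 0.00137) and 0.45 (11 of 13 lower, adjusted p = 0.00152). These 3 calls were lost (adjusted p = 0.851 with an estimated correlation for each). The interferon call ended without saline male 24 (adjusted p = 0.062) and the macrophage call without saline female 47 (adjusted p = 0.0854).

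Under oxycodone the sexes differed in 9 genes, 5 higher and 4 lower in males, and 7 of them were also called under saline. Xist fell by 5.82 on the log2 scale and Eif2s3x by 0.52 (adjusted p = 0.00162). Ogt, the enzyme that adds N-acetylglucosamine to proteins, fell by 0.58 (adjusted p = 0.0321) and Taf1 by 0.57 (adjusted p = 0.0342), each below the female median in 11 of 11 males. Under saline Ogt and Taf1 were at -0.50 and -0.56 (adjusted p = 0.0732 and 0.0599), and the difference between the treatments did not pass for either. Kdm6a, Kdm5c and Ddx3x were at -0.04, -0.14 and -0.15. Limma-voom gave 16 genes and DESeq2 12, or 9 adjusted over the 17700. Of the lists, the prolactin family (-0.14), ribosomal proteins (-0.06) and decidual stroma markers (-0.25) fell and the yolk sac markers (0.26) rose in males, each at an adjusted p of 0.0327 (adjusted p = 0.955 with an estimated correlation). These calls ended in 11, 12, 12 and 15 of the 42 fits without 1 library, with adjusted p up to 0.273, 0.554, 0.189 and 0.473; without oxycodone female 12, 20 or 36, saline male 24 or oxycodone male 49 or 50, all 4 ended.

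The opioid receptor genes, among them Oprm1, the main receptor of oxycodone, had few counts. The filter removed them from the gene tests, and so from the test of their list. Oprm1 had 25 counts in total, in 17 of 42 libraries, Oprk1 20 counts in 10 libraries, Oprd1 151 counts in 39 libraries and Oprl1 48 counts in 25 libraries.

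The largest variation among libraries did not follow treatment or sex. The first principal component of log2 CPM held 31.7% of the variance, against 7.71% for the second. Libraries numbered up to 36 ran from -95.9 to 22.2 on it, and those numbered 43 and above from 17.8 to 41.2. The blocks held 4 and 6 saline females, 4 and 6 saline males, 6 and 5 oxycodone females, and 4 and 7 oxycodone males. Saline female 67 stood apart in uterine markers: its decidual score was 6.09 against 2.77 to 3.87 in the other 9 saline females, its natural killer score 6.15 against 3.31 to 5.18 and its uterine epithelium score 2.64 against 0.21 to 2.10. It also lay above the other saline females in the hypoxia, oxidative stress and steroid lists.

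**Figure D3:**
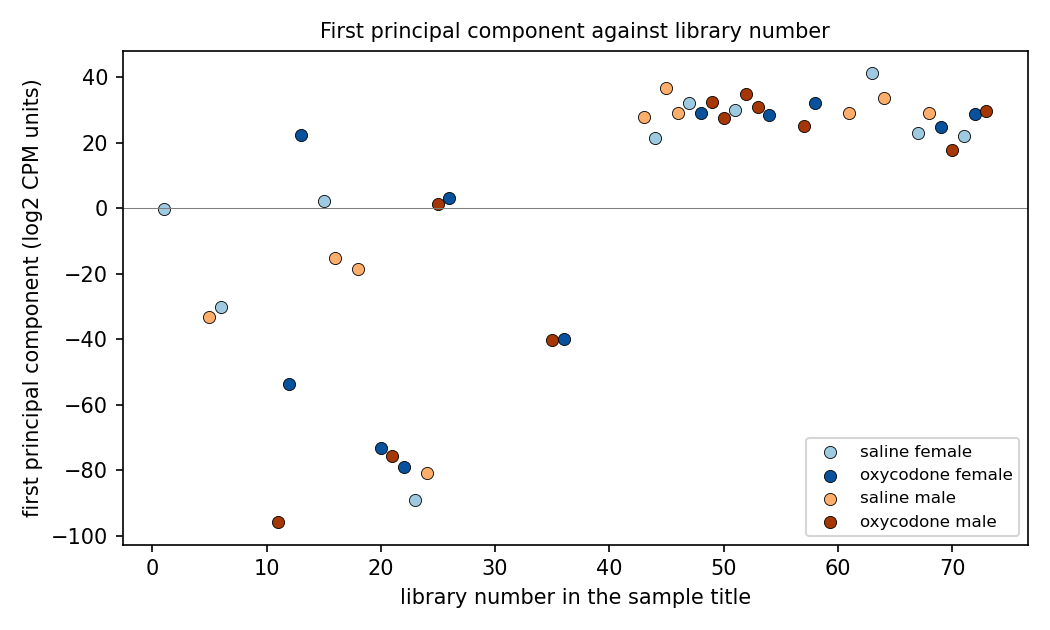
The first principal component of log2 CPM (31.7% of the variance) against the library number in the sample title, 1 point per library, coloured by group. Libraries numbered up to 36 run from -95.9 to 22.2 and those numbered 43 and above from 17.8 to 41.2.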

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

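The tests of yolk sac tissue amounts, of the junctional zone and decidual shares, of the block for the decrease in females, of transcript length, of the second index and of oxycodone or sex for the first principal component were chosen after the results were seen, as were the permutation of list scores and the values within blocks of library numbers.

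The visceral yolk sac markers differed in their oxycodone response between the sexes (adjusted p = 1.27e-52 with the preset correlation). Leaving out any single library kept at least 90.1% of the score difference of -2.62, and the difference was -1.69 in the block of library numbers where it was smaller and -3.26 in the other, which argues against a single library or the block as the whole cause of this difference; for the decrease in females the block stays open, since it was -2.37 in libraries numbered up to 36 and -0.0058 in those numbered 43 and above. Varying amounts of yolk sac tissue in the dissected pieces cannot be told apart from a change in the placenta: the markers moved together from library to library in 3 groups (median pairwise correlation 0.926, 0.928 and 0.900) but less so in saline males (0.471), where the score spanned 2.07 log2 units against 6.42 in saline females. The most abundant markers were Afp (555 CPM), Trf (207 CPM), Apob (58.6 CPM) and Apoa1 (49.9 CPM), and the largest difference between group means, 2.17, was smaller than the range within 3 of the 4 groups. A response to oxycodone that differs between the sexes can neither be shown nor excluded (permutation p = 0.0106, adjusted p = 0.381 over 36 lists), since the list was picked because of this difference and saline males and females already lay apart.

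The prolactin, glycoprotein and cathepsin lists were higher with oxycodone in females by the preset test (adjusted p = 0.247 with an estimated correlation for each). With the block of library numbers as a term, the mean log2 fold change of their 53 members went from 0.40 to 0.33, or 81.8% of its value. This argues against the block as the whole cause. With the decidual score as a term, that mean was 0.35, or 86.8%. Without saline female 67 the decidual markers were higher with oxycodone (0.55, adjusted p = 0.0242 with an estimated correlation). In those 20 female libraries the joint score kept 106% of its difference with the decidual score as a term. Within groups the 2 scores hardly went together (r = -0.045), which argues against decidual stroma, as scored, as the whole cause. Maternal tissue that this score misses was not tested, and Prl8a2 and Prl3c1 are on both the decidual and the prolactin list. A larger share of junctional zone, the layer that makes many of these products, cannot be told apart from a change within cells: the junctional zone markers had a mean of 0.16, or 40.5% of that of the 3 lists, with a score interval of -0.07 to 0.42. A response to oxycodone in females can neither be shown nor excluded (joint score difference 0.42, 95% bootstrap interval 0.04 to 0.80, permutation p = 0.0490), since the lists were picked because they were high and the smallest adjusted permutation p over 36 lists was 0.653. The labels do not say which placentas shared a dam, and a difference between litters was not tested.

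The first principal component parted the libraries numbered up to 36 from those numbered 43 and above, and the blocks held 66.4% of its variance, against 1.37% between the 4 groups, which argues against oxycodone or sex as its cause. Its gene loadings went with exon length (Spearman's rho 0.396) and with GC content (rho 0.323), and its library values with depth (Pearson's r 0.652 over 42 libraries, rho 0.662). Within the blocks the correlation with depth was 0.480 (permutation p = 0.0435, n = 18) and 0.457 (permutation p = 0.0252, n = 24), with rho of 0.445 (permutation p = 0.0662) and 0.389 (permutation p = 0.0624), and r was 0.612 without the 2 libraries farthest from the median depth. The 30 pairs of libraries numbered 1 apart had a mean residual correlation of 0.375, against 0.168 for the 399 other pairs of the same block (permutation p = 0.0001, the smallest that 10000 shuffles can give), with 0.423 for the 22 such pairs with the same treatment and 0.244 for the 8 with different treatment. A shared collection, preparation or litter may therefore account for part of the variation between libraries, in which case the libraries of a group are not independent and the p-values given here are too small; a second index in the sample titles, whose 2 ranges held 48.7% of the variance, cannot be told apart from the blocks, since saline males 43, 45 and 46, the only libraries it places with those numbered up to 36, lay above all 18 of these (permutation p = 0.000752) but are near neighbours, and the p was 0.0526, the smallest possible, over 19 runs of neighbouring libraries.

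Other splits of the libraries were compared with the real one, 100 in number unless stated. In the female, male and sex difference comparisons, with 0 genes in the real split, all 100 splits gave as many, and the highest others gave 2334, 1888 and 1816. Averaged over the sexes, 12 splits gave at least the real 1 gene, and the highest other gave 28, so chance cannot be excluded. For male against female placentas, 2 splits gave as many genes as the real one, the real one included, under saline (11, highest other 13) and under oxycodone (9, highest other 7237), which makes chance unlikely for these counts only if libraries are exchangeable. For the lists, 44 splits gave at least the real 10 in females (highest other 20), 90 at least the real 4 in males (highest other 19), 67 at least the real 8 on average (highest other 19) and 97 at least the real 3 for the sex difference (highest other 20), so chance cannot be excluded for the number of lists in any of these. With surrogate variables, 2 of 50 splits gave at least the real 14 genes in females (highest other 99). Taken alone, this makes chance unlikely for that count only if libraries are exchangeable, and libraries with neighbouring numbers were alike. The female count was also the largest of the comparisons, and other splits gave 201 genes in males and 42 and 539 for the sex difference. Chance therefore cannot be excluded for a count of this size in some comparison. The correlation of female and male fold changes was as high as the real 0.049 in 41 splits (highest other 0.502). The splits that called the most genes in these comparisons point to a structure of the samples. The splits with 2334 female and 1888 male genes had the largest difference of that sex on the first principal component (-49.0 and 40.7), and the split with 1816 genes had the most opposed pair (-46.0 in females, 21.01 in males). Such a difference was neither enough nor needed. Of the 9 splits other than the real one that were parted by more than 30 in females, only that with 2334 genes had a female gene. The split with 67 female genes was parted by -29.8, and that with 57 by -1.47. The count of female genes had a rho of -0.109 with the size of the difference over the 99 other splits, 88 of them with 0 genes.

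In the groups of 10 libraries, 125 sets of values were tested for a library far from the others. The measure was its gap divided by the range, against a limit of 0.466, and 20 passed. Only the saline groups held 10 libraries, so the oxycodone groups were not tested in this way and may also hold such libraries. Chance gives about 1 in 20 for independent sets, but these sets were correlated and held genes named for a small p, so the number says nothing about chance. Saline female 67 lay apart in Cxcl14 (0.793), Klk15 (0.535) and Anxa8 (0.557), genes whose small p came from that library. Saline female 44 lay apart in the yolk sac score (0.481), Apoa4 (0.535), Cfi (0.503) and Afp (0.581). Saline female 23 lay apart in Xist (0.513), Ogt (0.762), Ddx3x (0.538) and Urod (0.558). Saline male 24 lay apart in Prkcq (0.530), Ddx3y (0.576), Xist (0.5), Ogt (0.472), Ddx3x (0.613) and Urod (0.537). Stmn2 in saline male 5 (0.489), Hbb-bh0 in saline male 64 (0.491) and Kdm5d in saline male 16 (0.470) also lay apart. The oxycodone response of the prolactin family (adjusted p = 1.13e-05; adjusted p = 0.784 with an estimated correlation) and of the glycoproteins (adjusted p = 0.00187; adjusted p = 0.949 with an estimated correlation) differed between the sexes by the preset test, with means of 0.24 and 0.25. Neither held in both blocks (prolactin family -0.07 and 0.39, glycoproteins 0.07 and 0.30).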

How the results depend on the processing

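The alternatives chosen after seeing the data were the legacy method with robust estimates, the number block as a term, each block alone, the yolk sac score, the fit without saline female 67, alone or with an estimated correlation, the DESeq2 Wald test adjusted over the genes of the filter, the list counts without each library and the permutation of list scores. Of 2219 values of named genes under other settings, 2202 kept their direction and 2127 their side of the threshold. Most of these genes were not past the threshold in the main test, so keeping their side was nearly fixed beforehand. The settings also share the same libraries, so these totals do not measure whether a result would repeat. The alternative without libraries whose sex genes go against the label gave no value, since 0 libraries did so. No paired analysis was possible because each library number occurs once. The filter on low counts removed the opioid receptors from the gene tests. Except where the construction of the alternative shows it, the cause was not tested.

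The count of genes in females, 0, became 2 without a filter on low counts, 14 with surrogate variables and 1 in the libraries numbered up to 36. The count averaged over the sexes, 1, became 3 with the DESeq2 Wald test, 2 with it adjusted over the 17700 genes of the filter, 2 without a filter on low counts, 2 with surrogate variables and 2 in the libraries numbered up to 36. It became 0 with the legacy quasi-likelihood without robust estimates, the legacy quasi-likelihood with robust estimates, a mean CPM of at least 1, the decidual score, the erythroid score, the fold minimum of 1.2 and the libraries numbered 43 and above. Under saline, the 11 genes between the sexes became 116 with the DESeq2 Wald test, 103 with it adjusted over the 17700 genes, 20 with limma-voom, 6 with the legacy method without and 6 with robust estimates, 21 without a filter, 58 with only the groups compared, 19 with surrogate variables, 7 with the erythroid score, 7 with the fold minimum of 1.2, 26 with the number block and 5 in the libraries numbered up to 36. Under oxycodone, the 9 genes became 16 with limma-voom, 22 with surrogate variables and 5 in the libraries numbered up to 36. Smaller changes of a count are left out here, such as 6 genes under oxycodone with the fold minimum of 1.2 and 15 under saline without saline female 67. Without each library in turn, the counts were 0 to 0 in females, in males and for the sex difference, 0 to 1 on average, 6 to 107 under saline and 7 to 9 under oxycodone.

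The counts of lists were 10 in females, 4 in males, 8 on average, 3 for the sex difference, 4 under saline and 4 under oxycodone. Smaller changes are again left out. With an estimated correlation they became 0, 1, 0, 1, 1 and 0, and with fry in place of camera 0 in each. The permutation of list scores, run for the first 4, gave 0 in each. In females it was 1, the decidual stroma markers, without saline female 67 and with an estimated correlation. In males the count was 11 with surrogate variables, 11 in the libraries numbered up to 36 and 7 with the yolk sac score. For the sex difference it was 9 with surrogate variables, 8 with the number block, 6 in the libraries numbered up to 36, 7 in those numbered 43 and above and 5 without saline female 67. Under saline it was 1 in the libraries numbered up to 36, 9 in those numbered 43 and above and 1 with the yolk sac score, and under oxycodone it was 0 with the yolk sac score. Without each library in turn, the counts were 6 to 12 in females, 1 to 7 in males, 7 to 11 on average, 2 to 5 for the sex difference, 3 to 8 under saline and 0 to 7 under oxycodone.

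The yolk sac score as a term removes the yolk sac signal by construction. With it, the yolk sac list had means of -0.0071 in females, -0.0037 in males and -0.0034 for the sex difference, where the test turned, the glycoprotein list had -0.0098 for the sex difference, Hnf4a 0.0074 in females, Fgb 0.15 for the sex difference, and Afp 0.34 in females, -0.17 in males and 0.51 for the sex difference. In the libraries numbered 43 and above, the test of the male cathepsins turned (mean 0.17), as did the natural killer list (-0.16) and Gzma (-0.45) on average. In those numbered up to 36, the prolactin list turned for the sex difference (-0.0659). With surrogate variables, the average of the natural killer list was -0.0262. Gzma was at -0.033 with limma-voom. Klk15 in females was at 0.12 with the DESeq2 Wald test and 0.15 without saline female 67. Kdm6a between the sexes under saline, 0.01, was at -0.0052 with a mean CPM of at least 1, -0.11 with surrogate variables, -0.019 with the erythroid score, -0.0031 with the number block, -0.11 in the libraries numbered up to 36 and -0.055 with the yolk sac score, and under oxycodone, -0.04, at 0.031 with limma-voom. Ddx3x under saline was at -0.029 with surrogate variables. The correlation of female and male fold changes, 0.049, was -0.0182 with the decidual score and -0.027 with the number block.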

Other observations

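The genes of this part were chosen after their values were seen. With surrogate variables, 14 genes passed in females, at adjusted p-values of 0.0236 to 0.0376, where 0 passed without them; the first surrogate variable had a correlation of 0.99995 with the first principal component. Higher with oxycodone were the retinol dehydrogenase Rdh10 (0.25), the endothelial receptor Tek (0.30), Mgst1 (0.77), the transporters Slc22a18 (0.36), Slc16a10 (0.34) and Slc7a2 (0.47), Tspan7 (0.43), Phf6 (0.36), Vnn1 (0.39) and Hacd2 (0.27). Lower were Gm14253 (-5.03), the heme synthesis enzyme Urod (-0.17), the kinase Eef2k (-0.23) and Arvcf (-0.29). Averaged over the sexes, Urod (-0.14, adjusted p = 0.00531) and Gm14253 (-3.73, adjusted p = 0.0116) passed with surrogate variables. Without them the adjusted p of Tek was 0.9996 with a log2 fold change of 0.11.

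Trim68, Hbb-bh0 and Trim12c, all lower with oxycodone on average as values, lie within 1.68 megabases of chromosome 7, from 102677582 to 104353362. That span, drawn around these 3 genes, holds 12 tested genes, of which 7 had a negative average log2 fold change, these 3 included. The 3 with an unadjusted p under 0.05 were the same genes, which had been named for a small p. That count was therefore fixed beforehand and says nothing about a local cluster. Trim12c exceeded 5 CPM in 8 of 10 saline females, 8 of 10 saline males, 4 of 11 oxycodone females and 3 of 11 oxycodone males. The stock is outbred, and inherited variation at this locus was not tested.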
